A study of Streptococcus salivarius with 5 samples.

How the data were processed

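The series holds RNA of Streptococcus salivarius HSISS4, a streptococcus of the human gut and mouth, in 5 libraries. Per the labels, 3 strains (the wild type, a comR deletion and a comX deletion) were grown in a chemically defined medium with glucose to an OD600 of 0.2 and then kept for 30 min with 1 µM sComS, the pheromone of the study. Their mRNA libraries were stranded, made after rRNA depletion, with 15 PCR cycles. Small RNA libraries of the wild type, kept for 30 min with DMSO or with 1 µM sComS, were made with a small RNA kit and 12 PCR cycles, size selected from 150 to 400 bp and sequenced as single reads of 76 nt, per the labels' protocols. Each of the 5 groups has 1 library, so nothing here has a replicate.

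The mRNA table holds raw read counts of 1903 coding genes in the 3 strains, as deposited by the authors, with gene symbols, locus tags, products and positions on the HSISS4 chromosome. The same table holds the authors' deposited ratios of each deletion to the wild type and the log10 of those ratios. Recomputed from the counts and the library totals printed in the table, the authors' ratio of each deletion equalled reads over total reads for 1903 of 1903 genes within a tolerance of 1e-06. The small RNA table holds raw counts of 42020 consecutive windows of 50 bp as deposited by the authors, without strand. Its normalised signal was the count over the library total (CPM) in all 42020 windows, within the same tolerance, per the file headers and the totals printed there, and its ratio of sComS to DMSO was deposited by the authors as well. The authors' ratios, log10 values and normalised signal were used only for this check and for the CPM levels of the small RNA libraries. SAMtools 0.1.18 is named in the submitters' processing notes. The aligner, the counting program and the handling of reads that match several places are not given in the sources used here, so values of near-identical gene copies, such as transposases and choline-binding proteins, are uncertain, as are values of overlapping genes.

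The mRNA counts summed to 48724386 (wild type), 39443058 (comR deletion) and 30440344 (comX deletion), which is 95.1%, 97.6% and 95.1% of the printed totals. The small RNA windows summed to 1.98 and 1.99 times the printed library totals of 34997305 (DMSO) and 14553127 (sComS) reads. A read that crosses a window border therefore stands in more than 1 window, and neighbouring windows share reads. The "upstream" and "downstream" entries of the small RNA table describe where the nearest feature lies: in all 3076 windows beside a gene of the mRNA table, "downstream" meant that the window lay on the 5′ side of that gene. Small RNA reads of a gene are the sum of the windows that the table marks as overlapping it.

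Counts were scaled with trimmed means of M values (TMM, edgeR 4.0.16 in R 4.3.3) over the 3 mRNA libraries and over the 2 small RNA libraries. The TMM factors were 0.987, 1.13 and 0.893 for the mRNA of the wild type, the comR deletion and the comX deletion, and 1.10 and 0.907 for the small RNA with DMSO and with sComS. A gene or window entered a comparison with at least 20 counts in 1 of the libraries compared. No value was added before a ratio, and a count of 0 was set to a floor of 3 counts, which is 0.0624, 0.0671 and 0.110 scaled CPM in the 3 mRNA libraries in the order above, and 0.0392 and 0.114 in the small RNA libraries with DMSO and sComS. Each fold has an exact (Clopper-Pearson) 95% interval from its 2 counts. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and say nothing of the spread between cultures. With 1 library per group no test was run and no p-value is given. Genes and windows at least 4-fold lower or higher are counted as a description of these libraries.

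The comparisons, the fold threshold of 4, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are comR and comX, the 12 lowest and 6 highest folds of each deletion against the wild type, the 5 lowest and 5 highest folds of the comR against the comX deletion, the 10 lowest folds of the class lower in the comR and not in the comX deletion, up to 4 members of each list with the largest fold in the comR deletion, and the 8 highest and 8 lowest small RNA windows. Other genes named in the text were chosen after their values were seen, and the text says so. The 15 gene lists were matched by gene symbol and product words. The rule that lets a symbol carry a copy number, and a word boundary before "phage", were set after seeing which genes matched, since a looser rule put comEA, comEB and comEC among the regulators and a macrophage infectivity protein among the phage genes. Planned lists of rRNA, tRNA and structured RNAs gave no values, because the files name none of these; 86 features with the prefix HSISS4_r, whose kind the files do not state, were treated as the rRNA and tRNA features. A list's median log2 fold is given with its percentile among 10000 random lists of the same size, matched on mean expression in deciles, as a description of these libraries. The random lists hold scattered genes, so percentiles and medians' intervals of lists made of neighbouring genes, such as urease, are too extreme and too narrow.

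Both deletions were compared with the same wild-type library, so their folds share its chance values. The overlap of their lower genes was set beside the product of the 2 counts over the genes compared and beside 100 simulations of unchanged libraries. The spread of the simulated libraries was first taken from the comX comparison for all 3 libraries. A second setting, in which each comparison kept its own spread, was added after the first result had been seen, because the first gave the comR comparison a far wider spread than it has. Random lists for the genes that are lower in the comR and not in the comX deletion were first drawn from all genes and then, after that value had been seen, only from genes under the same limit in the comX deletion. They were last drawn, again after the values had been seen, as runs of neighbouring genes of the same sizes and of similar level, since neighbours move together.

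The alternatives planned were median-of-ratios size factors (DESeq2 1.42.0), total counts and ribosomal protein genes as scaling, no filter or at least 100 counts, fold thresholds of 2 and 8, 0.5 or 5 counts added, counting intervals wholly past the threshold, other limits for the class not lower in the comX deletion, unmatched random lists, lists by symbol alone, and windows summed per nearest feature and side. Adjacent small RNA features were to be merged per strand, and the files give no strand, so this sum took their place. Scaling by the printed library totals, and a class that uses the small RNA libraries in place of the comX deletion, were added after seeing the data. On simulated data with the real means and depths, changes of 8-fold and 32-fold were past the 4-fold threshold in 100% of the changed genes and windows and changes of 2-fold in 0%, in each of the comparisons simulated (1900 genes for the comR deletion, 1896 for the comX deletion, 33604 windows). Of the unchanged features, 0% of genes and 0.159% of windows passed it. These simulated counts varied by counting error alone. Without a spread between cultures or libraries, the shares say nothing of how many calls that spread would give. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.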

Results

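The study asked how the transcriptome of S. salivarius HSISS4 responds to the competence pheromone, and which part of it needs ComR, the regulator that senses the peptide, and which part needs ComX, the sigma factor of late competence genes. Messenger RNA was read in 3 strains given 1 µM sComS for 30 min (wild type, comR deletion, comX deletion) and small RNA in the wild type given DMSO or sComS. The mRNA libraries held 48724386, 39443058 and 30440344 gene reads for the wild type, the comR deletion and the comX deletion, with a median of 8696, 7485 and 4638 reads per gene. The small RNA libraries held 34997305 reads with DMSO and 14553127 with sComS. There was 1 library per group and no replicate, so no difference below has a replicate check, and the intervals given cover counting error only. Gene names, products and positions are those of the files, on the HSISS4 chromosome.

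The deleted genes stood as the labels say. Reads of comR (HSISS4_00217, 248145 to 249044, plus strand) were 4533 in the wild type, 1 in the comR deletion and 4104 in the comX deletion. Reads of comX (HSISS4_00102, 127262 to 127759, plus strand) were 33197 in the wild type, 1052 in the comR deletion and 58 in the comX deletion. The log2 fold of comX in the comR deletion was -4.87 (95% counting interval -4.96 to -4.79), a level 29.3-fold below the wild type.

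The comR deletion lacked most of the competence and bacteriocin transcripts of the wild type and differed little elsewhere. The genes lowest against the wild type, after comR, were 3 neighbouring genes for hypothetical proteins, HSISS4_01742, HSISS4_01743 and HSISS4_01744 (1949716 to 1950363, plus strand), which were 968-fold, 906-fold and 906-fold lower. The putative choline-binding protein gene cbpD1 was 630-fold lower, with 273971 reads in the wild type and 404 in the deletion. The bacteriocin gene blpK was 318-fold lower and the nearby immunity gene blpI 52.3-fold lower. The genes of an ABC transporter, HSISS4_00176 and HSISS4_00177, were 519-fold and 470-fold lower. Of 1899 genes with at least 20 reads, 69 were at least 4-fold lower, comR included, and 0 were at least 4-fold higher; 68 of the 69 had a counting interval wholly past 4-fold.

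Most other genes among the lowest in the comR deletion code for hypothetical proteins: HSISS4_01664 (592-fold lower) and HSISS4_01665 (484-fold) lie side by side at 1863675 to 1863997, HSISS4_01584 (533-fold, annotated as the disulfide reductase DsbD) and HSISS4_01585 (546-fold) lie between blpI and blpK, and HSISS4_01594 (528-fold) lies at 1788912 to 1789142. The highest genes stayed near 2-fold. They were ureB of the urease (log2 fold 1.21, interval 1.16 to 1.25), the phenylalanyl-tRNA synthetase gene pheS (1.11), the dipeptidyl-peptidase gene pepXP (1.04), and guaA1, HSISS4_00741 and HSISS4_00738 (1.03, 1.02 and 0.99), which the products describe as enzymes of histidine synthesis.

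By gene list, 18 of 24 late competence genes were at least 4-fold lower in the comR deletion and 0 higher, and the list's median log2 fold of -5.35 (median's interval -6.57 to -2.16) lay at percentile 0.0 of random lists. The 7 genes of the comG run, which code for the DNA uptake pseudopilus, lay between 94.1-fold (comGD) and 107-fold lower (HSISS4_01762, ComGF). The DNA channel gene comEC was 29.6-fold and the DNA translocase gene comFA 63.6-fold lower. Named after their values were seen, the 6 list members less than 4-fold lower were radA (-1.60), cinA (-0.98), recA (-0.90), HSISS4_01715 (-0.34), celB (-0.10) and ssbB (0.07). By their products celB is a cellobiose transporter and HSISS4_01715 a response regulator. By locus tag ssbB lies between the ribosomal protein genes rpsR and rpsF. The gene ssbA, which the list does not hold, was 339-fold lower. Membership follows names and product words, so the 24 members need not all be late competence genes. Of 4 regulators, comR, comX and comA were at least 4-fold lower, while mecA, a negative regulator of competence by its product, stood at 0.37. Of 5 bacteriocin genes 3 were lower (blpK, blpI and the transporter gene comA, 17.1-fold lower), and 2 CAAX protease genes stood at 0.07 (HSISS4_01404) and, named after its value was seen, -0.01 (HSISS4_00605).

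The other lists lay within 2-fold of the wild type at the median in the comR deletion. The 9 urease genes had the highest median, 0.79 (0.73 to 0.94), above all random lists, with 1 member at least 2-fold higher and 0 lower. Of these, ureC stood at 0.94, ureI and ureE at 0.87. Urease genes from ureI to ureE are neighbours on the plus strand (253608 to 257100), and same-strand neighbours move together (r of 0.609 in this comparison). The random lists hold scattered genes, so the percentile and interval of this list overstate its distance from them. Pyrimidine synthesis genes (14, median 0.33, percentile 99.9), glycolysis genes (11, median 0.28, percentile 99.3) and peptide uptake and peptidase genes (14, median 0.23, percentile 99.5) also lay at the upper end, with 0 members at least 4-fold higher or lower. In the last list pepA was 3.20-fold lower. The ribosomal protein median was 0.12 (54 genes, percentile 97.7), which became -0.025 with ribosomal proteins themselves as the reference. Heat shock and Clp genes (16) had a median of -0.16 (percentile 4.84) and purine genes (15) one of -0.14 (percentile 7.54), both above 0 under total-count scaling and with the printed library totals. SOS and repair genes (23, percentile 76.1), lactose and galactose genes (8, 90.4), amino acid synthesis genes (50, 81.2), cell division and wall genes (28, 86.9) and phage and mobile element genes (36 measured, 42.3) lay within the random lists, and the sign of their medians depended on the scaling except for lactose and galactose. Single members at least 4-fold lower were recX among the repair genes (18.3-fold), gltA for citrate synthase (5.91-fold) and the phage-related HSISS4_00658 (4.53-fold, though -1.98 on the log2 scale with total-count scaling). The cell division pair ftsE and ftsX was 2.39-fold and 2.32-fold lower.

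The comX deletion also lacked the late competence transcripts, but kept or exceeded the wild-type level of the bacteriocin genes. The gene cbpD1 was 3872-fold lower, with 40 reads against 273971. The gene ssbA, annotated as a tRNA-binding protein in the files, was 1877-fold lower and the pseudopilus genes comGB and comGC were 1137-fold and 1124-fold lower. By contrast blpK was 4.72-fold higher than in the wild type, blpI 2.81-fold higher and comA 1.93-fold higher. The log2 fold of blpK was 1.64, under 4-fold, with ribosomal proteins as the reference. The hypothetical gene HSISS4_01665 was the highest of all genes at 9.52-fold (log2 fold 3.25, interval 3.24 to 3.26), under each of the 5 scalings above the wild type.

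Of 1899 genes, 148 were at least 4-fold lower in the comX deletion and 54 higher, of which 130 and 51 had counting intervals wholly past 4-fold. The folds of all genes spread far more widely than in the comR deletion, with a robust SD of 1.23 against 0.32 on the log2 scale, and 413 genes were at least 2-fold lower and 351 at least 2-fold higher. The split depended on the scaling: with ribosomal protein genes as the reference it was 265 lower and 11 higher. That reference moved the median of all genes by -0.59 in this comparison and by -0.14 in the comR deletion, total-count scaling moved them by -0.14 and 0.20, and the printed library totals by -0.14 and 0.24. The 12 lowest genes were cbpD1, ssbA, comX, comEC (247-fold lower), comFA (209-fold lower) and the 7 genes of the comG run. The next highest after HSISS4_01665 were potA2 (9.07-fold, an ABC transporter ATPase), HSISS4_00170 (8.06-fold), HSISS4_01078 (7.88-fold), asnA for asparagine synthesis (7.79-fold) and rpmF for ribosomal protein L32 (6.84-fold).

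**Figure D1:**
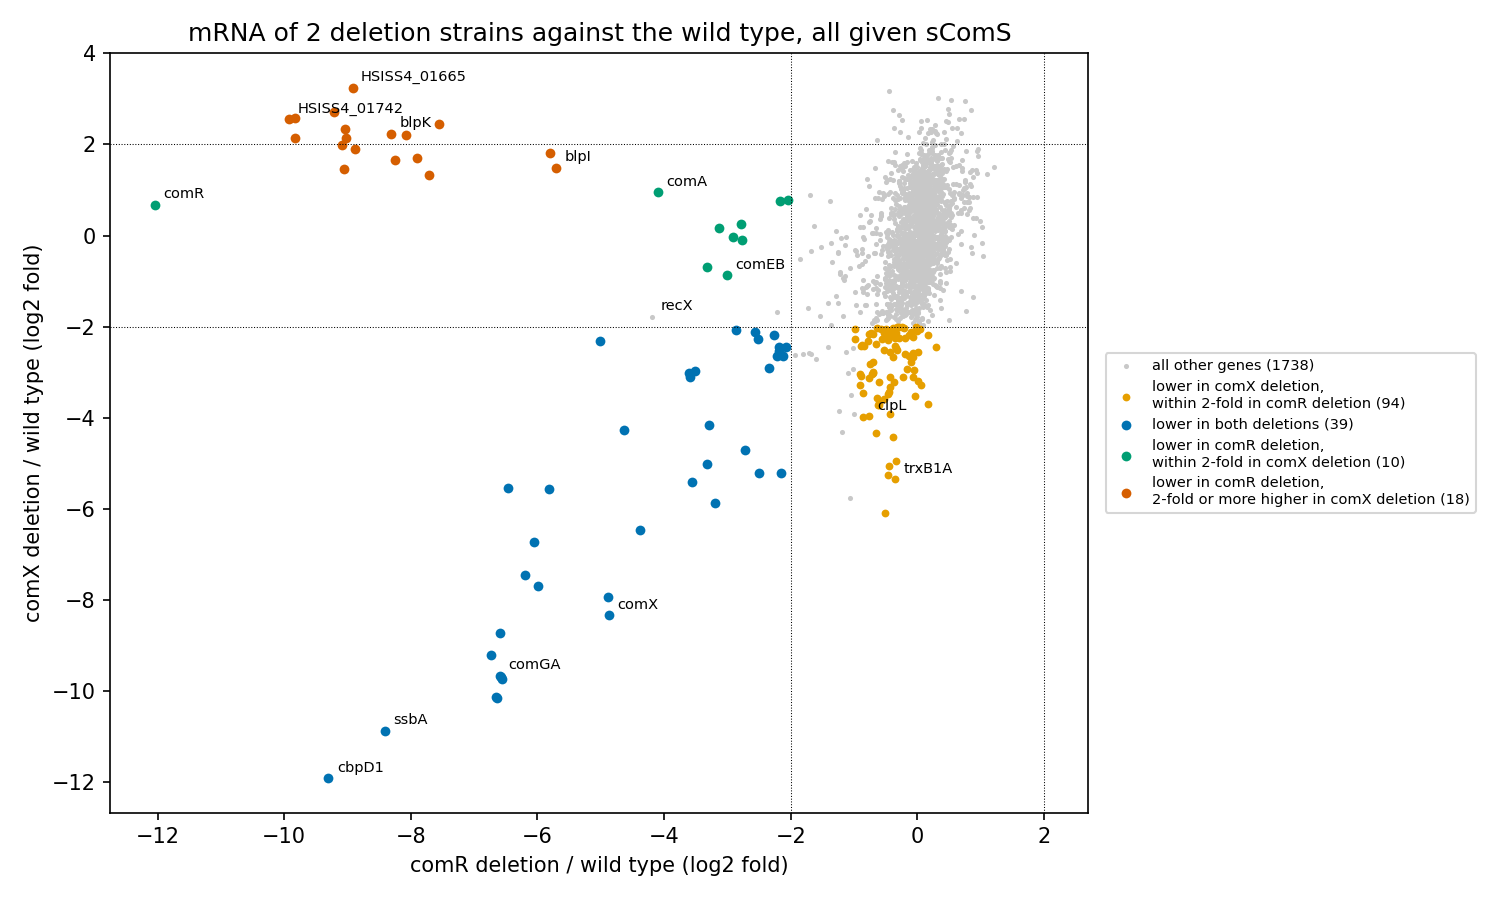
Log2 fold of each gene's mRNA in the comR deletion (x) and in the comX deletion (y) against the wild type, 1 library per strain, for genes with at least 20 reads; dotted lines mark 4-fold and colours mark the classes of the text. The 39 genes lower in both deletions fall at the lower left and the 18 genes that exceed the wild type in the comX deletion at the upper left, under TMM scaling.

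In the comX deletion 18 of 24 late competence genes were at least 4-fold lower and the list's median was -6.01 (-9.22 to -2.71), at percentile 0.0. Heat shock and Clp genes had a median of -0.73 (-1.47 to -0.24, percentile 0.65), with 7 of 16 at least 2-fold lower and 2 higher: the Clp ATPase gene clpL was 15.7-fold lower (2600704 reads in the wild type, 93676 here), groEL 3.13-fold and dnaK1 2.15-fold. Amino acid synthesis genes had a median of -0.65 (percentile 0.17), with 14 of 50 at least 2-fold lower and 6 higher, and SOS and repair genes one of -0.54 (percentile 2.16), with 5 of 23 lower and 1 higher. Urease genes lay high here too (median 0.93, percentile 98.4, 4 of 9 at least 2-fold higher, ureB 2.83-fold). Ribosomal protein genes (median 0.64, percentile 81.6) and glycolysis genes (1.03, percentile 83.8) lay within the random lists, although 17 of 54 and 6 of 11 were at least 2-fold higher, among them rpmF, rpmE2 (5.91-fold) and tpiA (5.13-fold). Percentiles of the others were 82.9 (regulators), 85.0 (bacteriocins), 15.3 (purines), 16.5 (pyrimidines), 71.1 (lactose and galactose), 34.2 (peptides), 81.7 (cell division and wall) and 96.6 (phage and mobile elements), with signs of the last 4 medians that depended on the scaling. Members of these at least 4-fold apart were comX and blpK, 1 of 15 purine genes lower, 1 of 14 pyrimidine and 1 of 14 peptide genes higher, and 2 of 36 phage and mobile genes lower (HSISS4_00658, 5.42-fold). With ribosomal proteins as the reference, blpK (log2 fold 1.64) and the peptide gene amiA3C (1.42) came under 4-fold, and amiA3C also with total-count scaling (1.87).

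The comparisons together split the 69 genes that were lower in the comR deletion. In the comX deletion, 39 of them were at least 4-fold lower as well, 2 were 2-fold to 4-fold lower (recX and, named after its value was seen, HSISS4_01209), 10 were within 2-fold of the wild type and 18 were at least 2-fold above it. The fixed class of genes lower in the comR and not in the comX deletion held those 10: comR itself, comA, the neighbours pncB, nadE and HSISS4_00180 (8.80-fold, 6.79-fold and 7.54-fold lower in the comR deletion), comEB (8.01-fold), pepP (10.0-fold), HSISS4_00104 (6.90-fold), HSISS4_01620 (4.52-fold) and HSISS4_01621 (4.12-fold, a LytR-type response regulator). The last 2 were under 4-fold with total-count scaling (log2 folds of -1.98 and -1.84). By its 2-fold limit the class left out the 18 genes above the wild type, which lay in 6 runs of neighbouring genes and had a median log2 fold of -8.90 in the comR deletion and 2.14 in the comX deletion. They were 5 genes from blpI to blpK, HSISS4_01594, HSISS4_00176 and HSISS4_00177, HSISS4_01664 and HSISS4_01665, HSISS4_01742 to HSISS4_01744, and 5 genes from HSISS4_01649 to HSISS4_01653, named after their values were seen.

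The 39 genes shared by both deletions compare with 5.38 for independent lists of 69 and 148 among 1899 genes. Simulated unchanged libraries against 1 shared wild type gave 24.9 shared genes on average (at most 37) when all libraries had the spread of the comX comparison. That setting, though, also gave 98.8 lower genes in the comR deletion, where 69 were seen. In the comX deletion it gave 100.1 lower genes, where 148 were seen. When each comparison kept its own spread, the simulations gave 0.01 lower genes in the comR deletion and so 0 shared genes. A wild-type library with the spread of most genes thus gave no overlap, while larger chance values of single genes were not simulated. In the small RNA libraries, 36 of the 39 genes were at least 2-fold higher with sComS. Of the 1721 genes at least 4-fold lower in neither deletion, 37 were. This argues against the shared mRNA library as the source of most of the 39, with 1 small RNA library per group. The part of that library in the rest cannot be split. Whether the wild-type mRNA and small RNA with sComS came from the same culture is not known here, so chance values of a shared culture stay open. The 39 include comX, which is lower in the comX deletion because it was deleted.

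**Figure D2:**
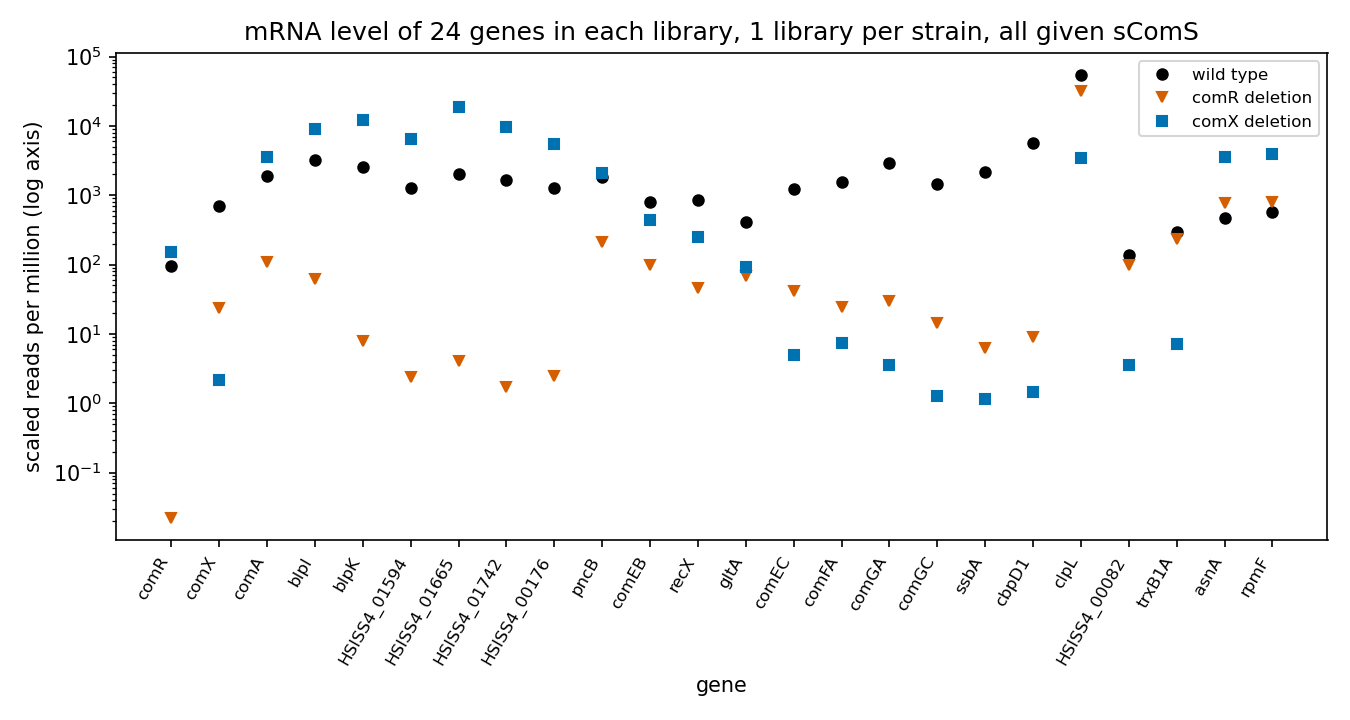
Scaled CPM (reads over the scaled library size, log axis) of 24 genes in the mRNA libraries of the wild type (circles), the comR deletion (triangles) and the comX deletion (squares), 1 library each. The genes from comA to HSISS4_00176 lie lowest in the comR deletion and highest in the comX deletion, while the genes from comEC to cbpD1 lie lowest in the comX deletion.

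Set against each other, the comR deletion had less of the bacteriocin and hypothetical transcripts and more of the late competence transcripts than the comX deletion. Lowest after comR were HSISS4_01742 (5669-fold lower), HSISS4_01743 (5392-fold), HSISS4_01665 (4609-fold) and HSISS4_01744 (3977-fold). Highest were the membrane protein gene HSISS4_00753 (48.1-fold, from 474 reads in the comR deletion and 6 in the comX deletion), trxB1A for thioredoxin reductase (32.3-fold), its neighbour HSISS4_00082 (28.0-fold), HSISS4_00421 (26.2-fold) and trxA1A for thioredoxin (24.7-fold); in the comR deletion these lay within 2.08-fold of the wild type. The late competence list had a median of 1.71 (0.58 to 3.06, percentile 100), with 11 of 24 members at least 4-fold higher, such as comGB (11.5-fold), and 1 lower, comEB. Of 1896 genes, 64 were at least 4-fold lower and 83 higher. With total-count scaling the counts were 41 and 130, with ribosomal proteins as the reference 38 and 148, and with the printed library totals 41 and 134; these moved the median of all genes by 0.34, 0.45 and 0.38. Heat shock genes lay high (median 0.72, percentile 99.9, 5 of 16 at least 2-fold higher and 3 lower), with clpL 9.27-fold higher.

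In the small RNA of the wild type, sComS went with more reads over the same competence, bacteriocin and hypothetical genes. The 8 highest windows lay 5′ of genes annotated as hypothetical proteins or an ABC transporter, which are not in the competence or bacteriocin lists. What the hypothetical proteins do is not known from the annotation. Neighbouring windows share reads, and other windows lay close behind: the one at 1780551 to 1780600, 5′ of blpK, was 1828-fold higher, and the peak of the comG run 1245-fold. The highest window lay 22 bp 5′ of HSISS4_01653 (1852651 to 1852700), with 1002 reads with DMSO and 1381980 with sComS, a 4027-fold difference after scaling. This window alone held 9.50% of the reads of the sComS library and 0.00286% of those of the DMSO library. The next window (1852701 to 1852750) was 3721-fold higher. The windows at 1864101 to 1864150 and 1864151 to 1864200, 5′ of HSISS4_01665, were 2344-fold and 2588-fold higher, those at 206901 to 206950 and 206951 to 207000, 5′ of HSISS4_00176, were 2331-fold and 2376-fold higher, and those at 1852051 to 1852100 and 1852101 to 1852150, 5′ of HSISS4_01651, were 2184-fold and 2013-fold higher.

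**Figure D3:**
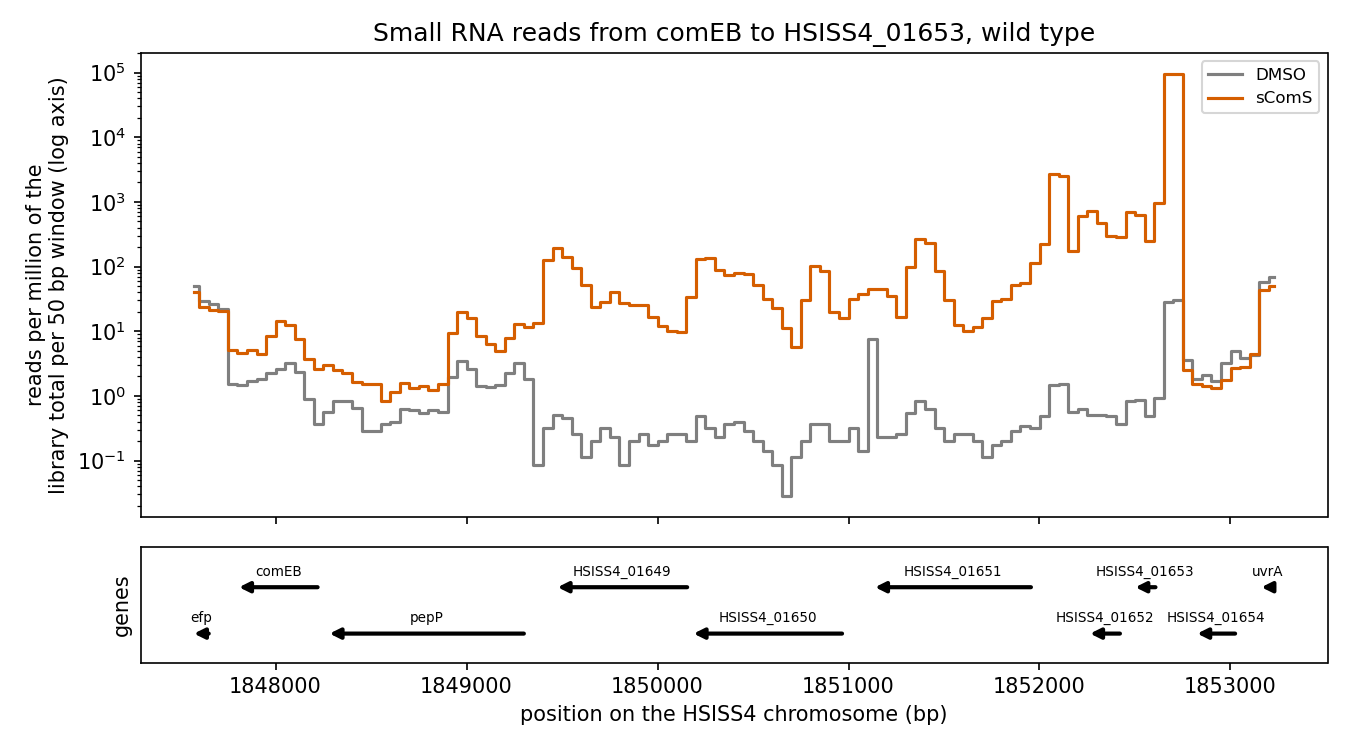
Small RNA CPM (reads over the library total) in each 50 bp window (log axis) from comEB to HSISS4_01653 in the wild type with DMSO (grey) and sComS (orange), 1 library each, with genes as arrows in their direction. The windows at 1852651 to 1852750, 5′ of HSISS4_01653, stand highest with sComS.

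Of 34045 windows with at least 20 reads, 1190 were at least 4-fold higher with sComS and 68 at least 4-fold lower. Of the higher windows 929 had an interval wholly past 4-fold and 1058 lay in 81 runs of at least 3 neighbouring windows, the longest of 94 windows over the comG genes (1961151 to 1965850). Windows in or next to genes at least 4-fold lower in the comR deletion made up 70.8% of the higher windows and 3.23% of all windows compared. None of the 68 lower windows had an interval past 4-fold. They held a median of 28 reads with DMSO, and the 8 lowest, at 23 to 29 reads with DMSO and 1 with sComS, gave log2 folds from -3.31 (-8.66 to -0.72) in HSISS4_01047 to -2.98 in HSISS4_00447, through windows of HSISS4_00083, HSISS4_00946, HSISS4_00966, HSISS4_01339 and pmrB and one beside HSISS4_01324. At this depth counting error alone leaves each of these windows open. The floor also shapes this ranking: a count of 0 was set to 3 while a count of 1 was kept. A window with 0 reads with sComS, as 470 windows had, thus ranks above one with 1 read at the same DMSO count. The count of 68 and the choice of the 8 lowest depend in part on that rule. Total-count scaling moved the median of all windows by -0.28 and gave 1047 higher and 150 lower windows, and the printed library totals gave 1048 and 150.

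Summed over genes, 60 of 1902 were at least 4-fold higher with sComS and 0 at least 4-fold lower, and 52 of the 60 were among the 69 genes at least 4-fold lower in the comR deletion, against 2.18 for independent lists. The gene blpK was 1552-fold higher, cbpD1 341-fold, comX 113-fold and comA 40.0-fold, whereas comR stood at a log2 fold of -0.01. The 18 genes above the wild type in the comX deletion had a median small RNA log2 fold of 8.99 (7.92 to 9.95) and the 39 genes lower in both deletions one of 2.96 (2.25 to 5.73). Among late competence genes 18 of 24 were at least 4-fold higher (median 5.08, percentile 100), and 3 of 5 bacteriocin genes (median 4.82, percentile 99.97) and 2 of 4 regulators (median 2.91, percentile 99.4). The 94 genes at least 4-fold lower in the comX deletion and within 2-fold of the wild type in the comR deletion (median there -0.43, 87 of them below the wild type) had a median of -0.04 (-0.13 to 0.00), with 0 at least 2-fold higher. The remaining lists had 0 members at least 4-fold apart in either direction; their percentiles ran from 1.56 (purines) and 1.97 (phage and mobile elements) through 4.04 (lactose and galactose), 7.86 (amino acids), 24.7 (urease), 45.1 (peptides), 50.6 (pyrimidines), 78.0 (glycolysis and heat shock), 93.7 (ribosomal proteins) and 96.2 (cell division and wall) to 97.9 (SOS and repair).

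**Figure D4:**
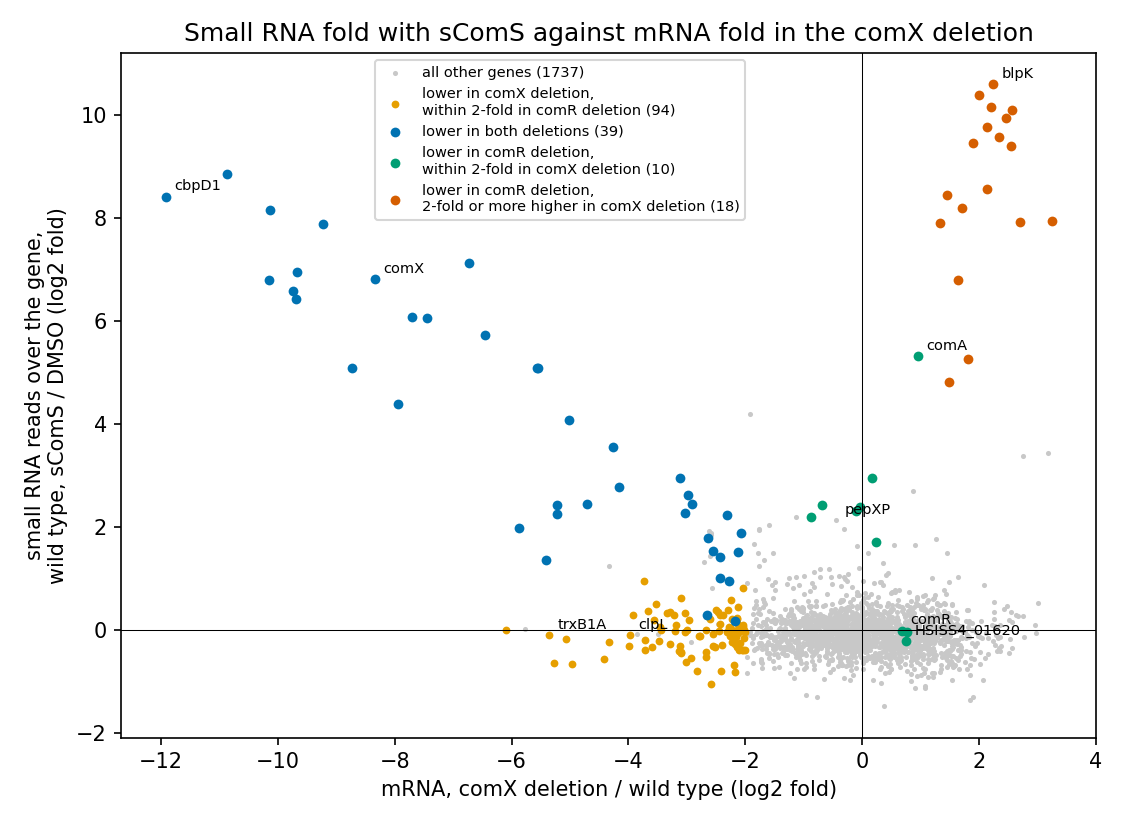
For each gene, the log2 fold of small RNA reads with sComS against DMSO in the wild type (y) and of mRNA in the comX deletion against the wild type (x), with the classes of the text in colour and 1 library per group. The 94 genes at least 4-fold lower in the comX deletion and within 2-fold of the wild type in the comR deletion lie around a small RNA fold of -0.04, and the 18 genes above the wild type in the comX deletion have a median of 8.99.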

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

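The tests in this part on scaling, spread, chromosomal runs, counting error, the comX culture and both tests on leftover late competence reads were chosen only after the results were seen; those on small RNA folds and gene length were not.

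Of the 69 genes at least 4-fold lower in the comR deletion, 39 were also at least 4-fold lower in the comX deletion, but 18 lay at least 2-fold above the wild type there, a difference between the deletions that was not tested, for lack of replicates. The lowest median of the 18 over the 5 scalings was a log2 fold of 1.54. This is no test of scaling, because the genes were chosen at least 2-fold higher and the largest shift by a scaling was -0.595. The wide spread of folds in this library as the whole cause is argued against by the median of all 28 genes lower in the comR and less than 2-fold lower in the comX deletion. That median, 1.68, lay at percentile 100 of random lists made of runs of neighbours of the same sizes under the same limit, the central 95% of which ended at 1.06, since neighbours on 1 strand move together (r of 0.554). A hypothesis is that ComX activity limits the ComR-dependent genes in the wild type: 24 of the 28 genes, and the medians of 9 of 9 runs or 7 of 9 with ribosomal proteins as the reference, lay above the wild type, while comEB (-0.87), pepP (-0.69), nadE (-0.10) and HSISS4_00180 (-0.04) did not. The 28 include the deleted gene comR (0.68), and HSISS4_01620 and HSISS4_01621, which form 1 of the 9 runs. Small RNA of these genes did not rise with sComS (log2 folds of -0.01, -0.22 and -0.04), so they add no support. HSISS4_00104 (0.25), which forms another of the 9 runs alone, lies near the deleted comX on the same strand. The gene between them, HSISS4_00103, stood at 2.42 in the comX deletion, and a local effect of the deletion was not tested. The hypothesis cannot be told apart from a difference of the comX culture or library, because there is 1 culture.

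A set of 94 genes was at least 4-fold lower in the comX deletion and within 2-fold of the wild type in the comR deletion, among them clpL, trxA1A, trxB1A and HSISS4_00753; in the comR deletion 87 of the 94 also lay below the wild type, with a median log2 fold of -0.435. If sComS induced them through ComX, their small RNA would be higher with sComS, but the median log2 fold was -0.042, far from the 2.96 of the genes lower in both deletions. Both classes were chosen by their level in the comR deletion, where comX was 29.3-fold lower. The contrast therefore largely follows from that choice and is a weak test. Gene length does not account for the 94 genes, as 90.4% stayed at least 4-fold lower after a trend on length was removed, nor does counting error, as 98.9% had an interval wholly past 2-fold and 81.9% past 4-fold. The robust SD of all folds in this library (1.23, against 0.316 in the comR deletion) leaves a difference of the comX culture or library as a candidate explanation, which cannot be told apart from an effect of the deletion that does not pass through sComS, because there is 1 culture. The wild-type library that both comparisons share may add to it, which was not tested.

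Late competence transcripts did not vanish in the comR deletion: the 18 list members at least 4-fold lower there kept a median of 1.25% of the wild-type level, and 0.442% in the comX deletion. Carry-over of wild-type reads is argued against by comR, of which the upper 95% counting limit was 0.132%, below even the lowest late gene at 0.159%. A level of transcription that needs ComX and not ComR is a hypothesis, under which the comX deletion would keep less: 83.3% of these genes had counting intervals above equal levels in the comR over the comX deletion, at a median of 4.98-fold, while comEB stood at -2.13 and, named after their values were seen, pilD at -0.92 and radC at -0.25. It cannot be told apart from a difference of the comX culture or library, because there is 1 culture.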

How the results depend on the processing

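The counts of genes and windows were recomputed under each setting, 1 change at a time; of 100 such values 64 were within 1.5 times the main count and 36 were not. The setting by the printed library totals and the class that uses the small RNA libraries were chosen after seeing the data. With a threshold of 2-fold, the larger counts follow from the looser limit: 111 lower and 5 higher genes in the comR deletion, 413 and 351 in the comX deletion, 329 and 355 between the deletions, 30 genes lower in the comR and not in the comX deletion, and 2298 higher and 1125 lower windows. With 8-fold the comX deletion had 68 lower and 3 higher genes, the comparison between the deletions 24 and 31, the class lower in the comR deletion alone 5, and the small RNA 756 higher and 7 lower windows. With ribosomal proteins as the reference the comX deletion had 265 lower and 11 higher genes, and the comparison between the deletions 38 and 148; there total counts gave 41 and 130, and the printed library totals 41 and 134. The class of 10 genes lower in the comR and not in the comX deletion held 4 within 1.5-fold, 30 when the limit was a level at least 4-fold below the comX deletion, and 52 when it was a 4-fold higher small RNA level with sComS. Of these 52, 28 were at least 4-fold lower in both deletions, so that set is not one of genes spared by the comX deletion. Higher windows numbered 781 with at least 100 counts and 123 after summing per nearest feature and side, which leaves fewer items. Lower windows numbered 150 with total counts, with totals without the HSISS4_r features and with the printed library totals, 185 with no filter, 1 with at least 100 counts, 2 after summing and 0 with 5 counts added, so they rest on low counts. The lower count of the comR deletion stayed between 60 and 71 under the 5 scalings. The ribosomal protein median in the comR deletion turned to -0.025 when those genes were the reference, by construction of that scaling. Of the named genes' calls recomputed under 4 scalings and with 0.5 counts added, 179 of the comR deletion and 170 of the comX deletion kept their side of 4-fold and direction, and 6 and 15 did not, each a fold that came under 4 without turning. Outside their counting interval lay 585 of the recomputed log2 folds of named genes, against 395 within it, and 26 list medians and 4 percentiles moved against 151 and 84 that did not. For other moved values the cause was not tested. No paired analysis was possible because each group has 1 library. Depth also limits the windows: 17977 of 42020 held under 20 reads with sComS and 8479 with DMSO.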

Other observations

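The genes of this part were chosen after their values were seen. Of the 39 genes at least 4-fold lower in both deletions, 17 were in the late competence list. Some of the others are given here. The neighbours citB (aconitase), gltA (citrate synthase) and icd (isocitrate dehydrogenase) had log2 folds of -2.87, -2.56 and -2.52 in the comR deletion and -2.07, -2.12 and -2.27 in the comX deletion, and their small RNA log2 folds with sComS were 1.88, 1.52 and 0.95. The type I DNA methyltransferase gene hsdM1 stood at -2.12 and -2.64, with 1.79 in the small RNA. Its fold in the comR deletion came under 4 with total-count scaling, a shift of 0.199. That of citB in the comX deletion did so with median-of-ratios size factors, a shift of 0.081. The tryptophan genes trpE, trpC and trpF, which are not among the genes lower in both deletions, had log2 folds of -0.87, -0.80 and -0.80 in the comR deletion and of -0.39, -1.14 and -1.29 in the comX deletion and were near 2-fold higher in the small RNA with sComS (1.04, 1.04 and 0.90).

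Among the 94 genes at least 4-fold lower in the comX deletion and within 2-fold of the wild type in the comR deletion were the anaerobic ribonucleotide reductase genes nrdD (log2 fold -3.21) and nrdG (-3.72), the copper ATPase gene copA3 (-2.67), the methionine synthesis gene metF (-3.73), and HSISS4_00079, HSISS4_00083 and HSISS4_00084 (-3.56, -4.96 and -4.42) beside trxA1A and trxB1A. In the comR deletion these lay between -0.63 (HSISS4_00079) and -0.10 (copA3).

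HSISS4_01620 and HSISS4_01621 were lower in the comR deletion without more small RNA reads with sComS (log2 folds of -0.22 and -0.04). They were not alone: comR stood at -0.01, HSISS4_00635 at 0.30, HSISS4_00748 at 0.17 and HSISS4_01209 at 0.15. Of the 69 genes lower in the comR deletion, 52 were at least 4-fold higher in the small RNA. Conversely 8 genes were at least 4-fold higher in the small RNA and not at least 4-fold lower in the comR deletion. Of these, HSISS4_00302, pepXP, HSISS4_01583 and HSISS4_01745 (log2 folds of 2.71, 2.13, 5.00 and 2.19) lie next to a gene lower in the comR deletion on the opposite strand. The windows carry no strand, so reads of the 2 genes cannot be told apart where they overlap. Next to such a gene lay 3.27% of all other genes. Position sets part of the signal apart: runs of higher windows in pepXP (1775451 to 1775800, peak 8.65-fold) and HSISS4_01745 (1950651 to 1951300, peak 37.0-fold) touched no gene lower in the comR deletion. HSISS4_01745 also lies next to ssbA, a lower gene on its own strand. The other 4 of the 8 were HSISS4_01493 (4.20), potA2 (3.43), HSISS4_01168 (3.38) and cbf (2.04), of which cbf was also lower in the mRNA, by less than 4-fold (-1.72 in the comR and -1.59 in the comX deletion). The neighbours potA2 and HSISS4_01168 were also higher in the comX deletion (3.18 and 2.76) and stood at -0.45 and -0.38 in the comR deletion.

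The most abundant small RNA windows with DMSO lay 5′ of tuf and rpsO. The windows at 458101 to 458150 and 458151 to 458200, 5′ of tuf for elongation factor Tu, held 20.8% and 21.5% of the reads with DMSO and 14.7% and 15.2% with sComS, with reads shared between them, and their log2 folds after scaling were -0.22 and -0.22. The window 5′ of rpsO at 149651 to 149700 held 6.44% and 3.68% (log2 fold -0.53). Between comR and comA, small RNA was level up to 249100 (log2 fold 0.40 at 249051 to 249100) and 16.7-fold higher with sComS at 249101 to 249150 and 43.0-fold at 249151 to 249200.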
